A study of Homo sapiens with 12 samples.

How the data were processed

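The deposited values came from 12 RNA-seq libraries of ZR-75-1 cells, an established estrogen receptor-positive breast cancer line. Per the labels, polyadenylated RNA was made into stranded Illumina libraries after 7 days of treatment. The 12 libraries formed 3 groups of 4. Parental cells received enobosarm, a selective androgen receptor modulator. Cells resistant to enobosarm received enobosarm alone or enobosarm with ruxolitinib, an inhibitor of the kinases JAK1 and JAK2. The drug doses are not given in the sources used here. Groups and replicate numbers were taken from the sample labels. The design text also names groups given vehicle or dihydrotestosterone, which are not analysed here.

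The authors deposited 1 table of whole-number read counts per gene, with no normalization. Per the submitters' processing notes, the tools and build used to make it include STAR 2.0 and the human build hg38. The counting program, the gene annotation and whether counting used the strand are not given in the sources used here, so overlapping and antisense genes cannot be separated with certainty, and reads shared by near-identical gene copies may be split between them. Small counts favoured even values. Among table entries holding 1 to 4 counts, 43.5% held the value 2 and 24.9% held the value 1. The table held 61552 gene identifiers, 61399 of which matched a symbol in the name table and 58352 a position in the GENCODE v29 annotation of GRCh38. Coordinates below are from that annotation. The total count per library ran from 42277739 to 65990619. Of the identifiers, 19224 had 0 counts in all 12 libraries.

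Counts were analysed as deposited in R 4.3.3. The edgeR filter filterByExpr, applied by group, removed 21032 further genes and left 21296 tested genes holding 99.94% of all counts. Libraries were scaled by TMM. Differences between groups were tested with edgeR 4.0.16 by its quasi-likelihood F test over all 12 libraries with a mean for each group and 9 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was a call. Counts with a log2 fold change of at least 1 in size are given as 2-fold changes. Log2 CPM values used a prior count of 2, whereas fitted log2 fold changes kept the edgeR default. Levels are CPM (counts per 1e6 counts of the TMM-scaled library size), given as mean ± SD of 4 libraries. Where all libraries of a group held 0 counts, the fold was computed against 3 counts over the group and is a lower bound, and where a group held 1 to 3 counts the ratio is given with its 95% counting interval. These bounds and intervals cover counting error only.

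A set of 27 gene lists was tested with camera in limma 3.58.1 on voom values, with the correlation between genes set to 0.01 and the Benjamini-Hochberg adjustment over the lists of a comparison. The lists covered androgen receptor targets, estrogen receptor targets, JAK-STAT pathway components, feedback and target genes of STAT3 and STAT5, the type I interferon response, antigen presentation with the interferon gamma response, NF-kB and inflammatory genes, luminal, basal, mesenchymal and neuroendocrine markers, stem and progenitor markers, the cell cycle, cell cycle inhibitors with p53 targets, apoptosis regulators, growth factor receptors and ligands, MAPK feedback and immediate early genes, cholesterol synthesis, fatty acid synthesis, glycolysis with hypoxia, oxidative phosphorylation, the unfolded protein and integrated stress response, steroid metabolism, steroid receptor coregulators, and markers of leukocytes, fibroblasts and endothelial cells. Members found under an older symbol were matched through the name table, and the entry SOD2 was not matched. Members were counted by their edgeR calls, adjusted over all genes and, separately, adjusted over the list alone.

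The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named, in each of the first 2 comparisons, the 10 largest rises and the 10 largest falls by fitted log2 fold change among called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between the 4 and 4 libraries. It also named 24 key genes of the receptor, JAK-STAT and lineage systems, up to 4 members of each list with the smallest adjusted p, and the 10 genes with the largest product of opposed changes in the first 2 comparisons. Some genes named by this rule are not reported here.

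The first 2 comparisons share the resistant libraries, so unchanged groups were simulated 20 times, with every group drawn from the resistant means. The shared libraries were also split in all 6 ways into 2 and 2. The pipeline was tested on simulated counts with 21296 genes. The changed genes, 100 for each size of change, were drawn only from genes above 2 CPM in the reference group, so lower genes were not covered. The pipeline called 94%, 94% and 92% of those changed by a log2 of 0.5 in the resistant against parental, ruxolitinib against no ruxolitinib and ruxolitinib-treated against parental simulations. Of those changed by a log2 of 1 it called 99%, 100% and 100%. Unchanged genes were called at 0.0427%, 0.057% and 0.0427%.

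The alternatives were DESeq2 size factors, library size alone, no low-count filter, a mean log2 CPM of at least 1, the DESeq2 1.42.0 Wald test, limma-voom, a fit of the 8 libraries compared, the replicate number as a block, each library left out in turn, an estimated correlation between genes and the fry test for lists, and the split shared libraries. After the data had been seen, 3 more were added, which were offsets for GC content and transcript length, parental replicate 4 and resistant replicate 2 left out together, and a filter at 1 CPM in a group of the comparison. GC content and length were those of the longest GENCODE v29 transcript. The offsets were tested on simulated counts of the ruxolitinib against no ruxolitinib comparison with 18893 genes. They lowered the unchanged genes called from 2.01% to 0.0482% and recovered 99.5% of changed genes, which were drawn from genes with a mean log2 CPM of at least 1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.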

Results

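Gene expression was measured by RNA-seq in ZR-75-1 cells, an estrogen receptor-positive breast cancer line, after 7 days of treatment. The 3 groups of 4 libraries were parental cells with enobosarm, resistant cells with enobosarm, and resistant cells with enobosarm and the JAK inhibitor ruxolitinib. Library totals were 47439785 to 63246317 counts in parental, 54575764 to 65990619 in resistant and 42277739 to 57201604 in ruxolitinib-treated libraries. The first principal component of log2 CPM held 94.0% of the variance. Libraries of a group correlated across genes at r = 0.989 to 0.992. Resistant and ruxolitinib-treated libraries correlated at 0.985 to 0.989, whereas parental libraries correlated with resistant ones at 0.69 to 0.709. Mitochondrially encoded genes took 13.2 ± 0.577% of counts in parental, 5.47 ± 0.598% in resistant and 4.97 ± 0.486% in ruxolitinib-treated libraries. No pair of replicates was identical or differed by less than sampling noise. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

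The first comparison asked how resistant cells differed from parental cells when both received enobosarm. Most luminal markers were lower in resistant cells, and most mesenchymal, inflammatory and stress response genes were higher. By camera, the luminal list was called with an estimated correlation (adjusted p = 0.0118), and the mesenchymal, NF-kB and stress response lists were not (0.203, 0.203 and 0.141). CDH1, which encodes E-cadherin, fell from 2233 ± 117 to 0.791 ± 0.0922 CPM, and VIM, which encodes the mesenchymal filament vimentin, rose from 0.228 ± 0.431 to 827 ± 45.3 CPM (n = 4 per group). The parental VIM mean rested on replicate 4, at 0.874 CPM against 0 to 0.0396 CPM in the others. In the GENCODE v29 annotation CDH1 (ENSG00000039068) lies on chromosome 16 at 68737225 to 68835548 and VIM (ENSG00000026025) on chromosome 10 at 17228259 to 17237593. Luminal markers were the list with the clearest fall, with 27 of 31 tested members down and 2 up.

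By edgeR, 9548 genes rose and 9080 fell at an adjusted p under 0.05, together 87.5% of the 21296 genes tested, and 6545 rises and 6325 falls were at least 2-fold. Among genes with a mean log2 CPM of at least 1 and no overlap between the groups, several of the largest rises started from 0 counts in every parental library. SERPINB9, an inhibitor of granzyme B, reached 52.1 ± 4.1 CPM, at least 3740-fold above parental. GALC, a lysosomal galactosidase, was at least 3720-fold higher, INSYN2B at least 3550-fold, the noncoding LINC00973 at least 2820-fold, PCBP3 at least 1790-fold, the growth factor gene PGF at least 1740-fold and SPANXC at least 1670-fold. COL8A1, a collagen gene, rose 12600-fold (counting interval 3490 to 104000), and CAV1, which encodes the caveolar protein caveolin, rose 11700-fold (3250 to 97000). SPANXB1 rose from 0.0334 ± 0.0437 to 331 ± 18.6 CPM. Without parental replicate 4 the parental mean was 0.0138 CPM for SPANXB1, and COL8A1 was at 0 counts. All parental CAV1 counts were in parental replicate 2, at 0.0387 CPM. The SPANX genes are near-identical copies, so their separate values are uncertain.

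By the same criteria the largest falls were in ALDH3B2, an aldehyde dehydrogenase gene, from 1182 ± 54.4 to 0.0904 ± 0.0997 CPM, and in APOD, a lipocalin gene, from 9806 ± 367 to 1.58 ± 1.75 CPM. The transporter gene ABCC11 changed by −11.52 on the log2 scale, CDH1 by −11.46 and the growth factor binding protein gene IGFBP5 by −11.17. FOXA1, a pioneer factor for steroid receptors, changed by −10.83 (edgeR adjusted p = 1.42e-30). RBM20, PADI2, TC2N and IGFBP2 completed the largest falls, at −10.79, −10.59, −10.15 and −10.09. The expression floor was a mean over all 12 libraries, 8 of them resistant. Genes at 0 counts in resistant cells therefore passed it less easily than genes at 0 counts in parental cells. HOXC10, for example, lay under it, with 134 ± 6.93 CPM in parental cells, 0 counts in resistant cells and a log2 change of −15.82.

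Luminal epithelial genes fell as a list (camera adjusted p = 6e-09), and this was the one list whose call held with an estimated correlation (adjusted p = 0.0118). On the log2 scale SPDEF, a luminal transcription factor, changed by −9.76, GATA3 by −5.07, PRLR, the prolactin receptor gene, by −6.92 and XBP1 by −4.46. ESR1, which encodes estrogen receptor alpha, fell from 18.3 ± 0.455 to 0.272 ± 0.147 CPM. PGR, the progesterone receptor gene, was low throughout and fell 47.4-fold (12.7 to 398) from 88 counts over the parental libraries. The keratin genes KRT8 and KRT18 changed by −1.52 and −1.51 and remained expressed, at 386.5 ± 9.22 and 132 ± 5.64 CPM in resistant cells. Of 34 tested estrogen receptor targets, 22 fell and 10 rose (camera adjusted p = 0.0172), and the estimated correlation gave an adjusted p of 0.203. CA12, a carbonic anhydrase gene, changed by −5.53 and NHERF1 by −4.12, whereas IRS1 rose by 3.49. Steroid metabolism genes also fell, with 23 of 35 down and 11 up (camera adjusted p = 0.0471, and 0.267 with an estimated correlation), a call that was lost when libraries were scaled by size alone (0.0579) and, after the data were seen, with GC and length offsets (0.0833) or without parental replicate 4 and resistant replicate 2 (0.051). SULT1A1, a sulfotransferase gene, fell by 8.92 and GSTP1, a glutathione transferase gene, rose by 11.29, or by 12.82 without parental replicate 4, which held 20 counts against 6 over the other 3.

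Mesenchymal markers rose in 26 of 31 members and fell in 4 (camera adjusted p = 4.13e-06, and 0.203 with an estimated correlation), including the matrix genes TGFBI (log2 11.29) and LOXL2 (10.80). Basal markers rose in 20 of 28 and fell in 7 (camera adjusted p = 0.013, and 0.0864 with an estimated correlation). The laminin gene LAMB3 rose by 6.66, while CDH3, which encodes P-cadherin, fell by 8.81. The basal keratin KRT5 was too low to test, and KRT14 rose from 0.0466 ± 0.0494 to 0.630 ± 0.212 CPM. In the MAPK feedback and immediate early list, 29 of 33 rose and 3 fell (camera adjusted p = 9.22e-08, and 0.0864 with an estimated correlation). FOSL1, an AP-1 factor, rose by 8.68, PHLDA1 by 10.09 and the phosphatase gene DUSP6 by 5.91.

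Antigen presentation and interferon gamma response genes rose in 36 of 39 and fell in 1 (camera adjusted p = 1.94e-09, and 0.0864 with an estimated correlation). HLA-B rose by 5.14, the class II chaperone gene CD74 by 4.81 and CD274, which encodes PD-L1, by 6.88 on the log2 scale. The HLA genes are similar in sequence and their division of reads is uncertain. Type I interferon genes rose in 32 of 46 and fell in 13 (camera adjusted p = 0.00762, and 0.0864 with an estimated correlation), with IFITM3 at 10.25 and LGALS3BP at 4.53. NF-kB and inflammatory genes rose in 30 of 39 and fell in 8 (camera adjusted p = 5.78e-05, and 0.203 with an estimated correlation). The cytokine gene IL1A rose by 10.94 and PLAU, which encodes urokinase, by 11.07, or by 11.71 and 12.09 without parental replicate 4.

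The unfolded protein and integrated stress response list had 29 of 35 up and 5 down (camera adjusted p = 4.13e-06, and 0.141 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 4.44 to 8384 ± 558 CPM, and PPP1R15A, a stress-induced phosphatase subunit gene, by 7.97. Glycolysis and hypoxia genes rose in 30 of 34 and fell in 3 (camera adjusted p = 9.64e-07, and 0.238 with an estimated correlation), with the peptide hormone gene ADM at 9.04, NDRG1 at 5.68 and HIF1A at 3.60.

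JAK-STAT pathway components were not called as a list, with 33 of 51 members up and 16 down (camera adjusted p = 0.0652, and 0.267 with an estimated correlation), but were called higher with the GC and length offsets (0.0361). The cytokine gene IL11 rose by 7.09, and IL6 rose from 0.0345 to 144 ± 16.9 CPM, with all 9 parental counts in parental replicate 4, so that without it parental IL6 was at 0 counts. JAK1 rose from 53.7 ± 2.05 to 213 ± 11.9 CPM, TYK2 by 0.94, STAT5A by 3.33, STAT5B by 1.06 and IL6ST, the shared receptor subunit of the IL6 family, by 1.80. JAK2 changed by −0.68 and STAT3 by −0.23. STAT3 and STAT5 feedback and target genes rose in 24 of 33 and fell in 9 (camera adjusted p = 0.0116, and 0.318 with an estimated correlation), and members of known JAK-STAT feedback went both ways. PIM1, a STAT-induced kinase gene, rose from 4.95 ± 0.11 to 543 ± 111 CPM and SOCS3, a feedback inhibitor gene, by 0.55. The feedback inhibitor genes CISH and SOCS2 changed by −4.55 and −3.62. The acute-phase gene SAA1, which shares reads with SAA2, rose by 6.85, TIMP1 by 8.33, and S100A9 fell by 12.36.

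Androgen receptor targets fell in 16 of 25 members and rose in 9, which was not called as a list (camera adjusted p = 0.103). FKBP5, a steroid receptor chaperone gene, changed by −2.30, the secreted protein genes PIP and AZGP1 by −11.75 and −7.11, and ELL2 rose by 3.32. Proliferation genes rose in 25 of 49 and fell in 17 (camera adjusted p = 0.345), and MKI67 fell by 0.43. The other lists were not called by camera. Rises and falls were 9 and 21 of 36 for oxidative phosphorylation, 12 and 22 of 38 for steroid receptor coregulators, 8 and 12 of 20 for neuroendocrine markers, 16 and 13 of 30 for stem markers, 16 and 13 of 31 for cell cycle inhibitors with p53 targets, 19 and 9 of 32 for apoptosis regulators, 20 and 18 of 41 for growth factor receptors and ligands, 13 and 13 of 26 for cholesterol synthesis and 17 and 14 of 31 for fatty acid synthesis. Markers of other cell types were also split, with 5 and 4 of 9 for leukocytes, 5 and 4 of 9 for fibroblasts and 8 and 4 of 12 for endothelial cells. Adjusted over the list alone, the counts differed only for oxidative phosphorylation, where 20 fell, and that list was called lower with the GC and length offsets (camera adjusted p = 0.0218). Camera's direction differed in sign from the median or the mean of 2 lists here, 7 lists with ruxolitinib and 1 list in the last comparison, none of which was called.

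**Figure D1:**
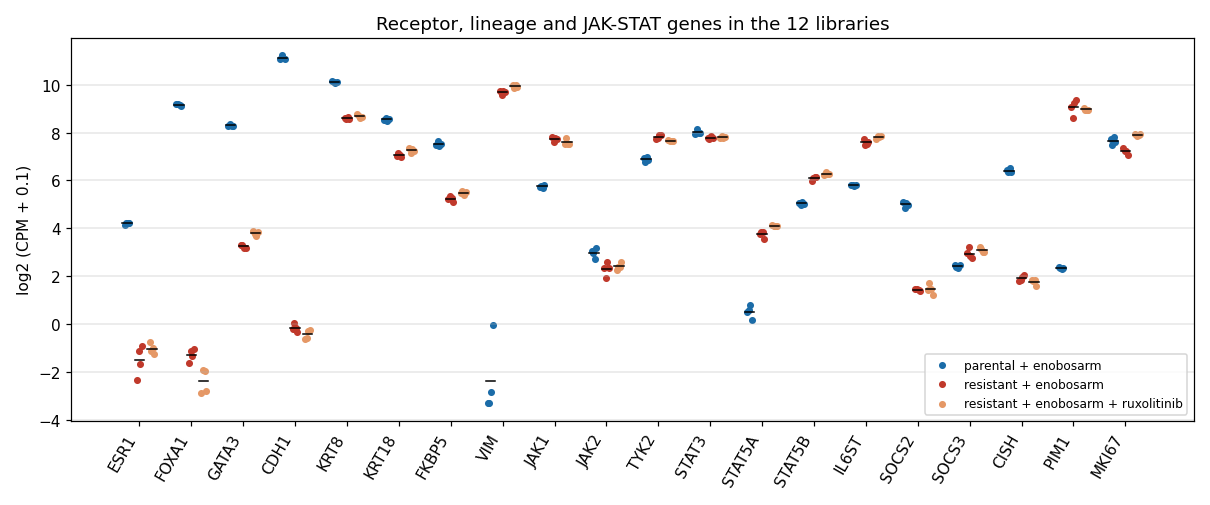
Expression of 20 receptor, lineage and JAK-STAT genes as log2(CPM + 0.1) on the vertical axis, with 1 point for each of the 12 libraries, coloured by group, and a bar at the mean of the 4 libraries. CISH fell and PIM1 rose between parental and resistant cells.

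The next comparison asked what ruxolitinib changed in resistant cells that kept receiving enobosarm. Proliferation genes were higher with ruxolitinib, in 44 of 49 tested members, and immediate early, stress response, antigen presentation and glycolysis genes were lower, the last in 19 of 34. None of these list calls by camera held with an estimated correlation (adjusted p = 0.0805 to 0.605). The changes were small, with a median size of 0.383 on the log2 scale among called genes. EGR1, an immediate early transcription factor, fell from 116 ± 15.1 to 23.2 ± 1.02 CPM, and MKI67, a marker of cycling cells, rose from 150 ± 11.5 to 239.9 ± 5.71 CPM (n = 4 per group). The JAK-STAT lists were not called.

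By edgeR, 3134 genes rose and 3945 fell at an adjusted p under 0.05, or 33.2% of those tested. Rises made up 44.3% of calls, and 60.1% (4246 rises and 2815 falls) when libraries were scaled by size alone. At least 2-fold changes were 331 in each direction, falling to 121 and 114 among genes with a mean of 1 CPM in either group. Among genes with a mean log2 CPM of at least 1 and no overlap between the groups, the largest rises were in CYP24A1, which degrades active vitamin D, from 11.2 ± 1.44 to 34.7 ± 2.62 CPM, and PLCB4, a phospholipase C gene, from 4.18 ± 0.339 to 12.9 ± 1 CPM. The oxytocin receptor gene OXTR rose by 1.44, the tight junction gene CLDN11 by 1.40, PTPRB by 1.39, the secreted protease gene ADAMTS1 by 1.37, CPA4 by 1.33, LINC01238 by 1.33 and the chemokine gene CXCL1 by 1.30 on the log2 scale. TGFB2, a growth factor gene, rose from 82.4 ± 8.8 to 199.5 ± 7.52 CPM.

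EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) had the largest change downward by the same criteria, of −2.33 on the log2 scale (edgeR adjusted p = 5.99e-16). Its approximate SE, the size of the change divided by the square root of the F statistic, was 0.0852. APOD, at 1.58 ± 1.75 and 0.190 ± 0.171 CPM, changed by −2.98 but overlapped between the groups. The gelatinase gene MMP9 changed by −2.17, the integrin gene ITGA1 by −1.81, the metalloproteinase inhibitor gene TIMP1 by −1.70, THBD, which encodes thrombomodulin, by −1.66 and PTGES, a prostaglandin E synthase gene, by −1.52. The stress cytokine gene GDF15 fell from 88.2 ± 13.6 to 29.04 ± 1.52 CPM and the oxidase gene NOX5 from 16.9 ± 5.13 to 5.56 ± 0.238 CPM. HSPA6, an inducible heat shock gene, fell from 42.8 ± 25.4 to 9.52 ± 1.47 CPM, with a wide spread without the drug. FOXA1 fell by 1.63 but lay near the floor, at 0.314 ± 0.0715 and 0.0992 ± 0.0684 CPM.

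Cell cycle genes were the list with the smallest p (camera adjusted p = 3.22e-21, and 0.259 with an estimated correlation), with 44 of 49 members up, 0 down and a median log2 change of 0.40. CDK1, the kinase that drives mitosis, rose by 0.57, the kinetochore motor gene CENPE by 0.65 and the checkpoint kinase gene BUB1B by 0.66. Basal markers rose in 14 of 28 and fell in 3 (camera adjusted p = 0.00365, and 0.0805 with an estimated correlation), with the integrin gene ITGA6 at 0.51, MYLK at 0.64 and COL17A1 at 0.79.

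MAPK feedback and immediate early genes fell in 20 of 33 members and rose in 0 (camera adjusted p = 4e-09, and 0.0927 with an estimated correlation). FOS changed by −1.21, the orphan receptor gene NR4A2 by −1.17 and SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, by −0.82. The unfolded protein and integrated stress response list fell in 24 of 35 and rose in 0, or 25 and 0 adjusted over the list alone (camera adjusted p = 6.54e-11, and 0.0805 with an estimated correlation). ATF4, the factor that drives the integrated stress response, changed by −0.52, its target gene TRIB3 by −0.80 and XBP1 by −0.65. Antigen presentation genes fell in 27 of 39 and rose in 2 (camera adjusted p = 9.14e-09, and 0.152 with an estimated correlation), with HLA-B at −0.63, HLA-C at −0.75 and GBP2 at −0.72, whereas CD274 rose by 0.77. Glycolysis and hypoxia genes fell in 19 of 34 and rose in 1, or 22 and 2 adjusted over the list alone (camera adjusted p = 0.000191, and 0.605 with an estimated correlation). The angiogenic factor gene VEGFA fell from 1447 ± 236 to 550.2 ± 22.5 CPM, ANGPTL4 changed by −0.85 and the glycolytic enzyme gene ALDOA by −0.52. Steroid metabolism genes fell in 11 of 35 and rose in 3 (camera adjusted p = 0.0292, and 0.343 with an estimated correlation). The near-identical AKR1C genes share reads, and AKR1C3 changed by −1.10, NQO1 by −0.75 and CYP1B1 by −0.52. The steroid metabolism call was lost without resistant replicate 1 (camera adjusted p = 0.0577).

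The lists of the pathway that ruxolitinib inhibits were not called by camera in either direction. JAK-STAT components rose in 9 of 51 and fell in 13, or 9 and 15 adjusted over the list alone (camera adjusted p = 0.79). IL7R, a cytokine receptor gene, rose by 1.24 and the cytokine gene LIF fell by 0.68. STAT3 and STAT5 feedback and target genes rose in 7 of 33 and fell in 7, or 8 and 8 adjusted over the list alone (camera adjusted p = 0.767), and SAA2 rose by 1.11. With the GC and length offsets rises and falls were 10 and 8 for JAK-STAT components (camera adjusted p = 0.899). They were 10 and 4 for the STAT3 and STAT5 list (0.49). SOCS3 stood at 7.65 ± 1.1 and 8.42 ± 0.605 CPM (edgeR adjusted p = 0.327, but called higher by 0.31 with the GC and length offsets, 0.0191), CISH at 3.64 ± 0.291 and 3.33 ± 0.262 (0.317), and SOCS2 at 2.60 ± 0.0924 and 2.67 ± 0.38 (0.833). STAT5A rose by 0.35, STAT5B by 0.18 and IL6ST by 0.21, STAT3 and JAK2 were not called, and TYK2 fell by 0.17 (edgeR adjusted p = 0.0191). TYK2's call ended without resistant replicate 3 or 4 or without ruxolitinib replicate 2, 3 or 4 (edgeR adjusted p = 0.054 to 0.0781), and STAT5B's ended without resistant replicate 1 (0.0558). With libraries scaled by size alone TYK2 was not called (edgeR adjusted p = 0.184), and with the GC and length offsets neither TYK2, whose change reversed to 0.02 (0.817), nor IL6ST, at 0.04 (0.532), was called. JAK1 stood at 213 ± 11.9 and 192 ± 16.4 CPM (edgeR adjusted p = 0.0622) and was called lower without resistant replicate 2 (0.0278) or ruxolitinib replicate 2 (0.00974), by limma-voom (0.0402) and with the offsets (0.046). PIM1 stood at 543 ± 111 and 499.9 ± 14.3 CPM (edgeR adjusted p = 0.339) and was called lower without resistant replicate 2 (0.00175). Type I interferon genes rose in 10 of 46 and fell in 12, or 11 and 12 adjusted over the list alone (camera adjusted p = 0.759).

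ESR1 stood at 0.272 ± 0.147 CPM without and 0.389 ± 0.0734 CPM with ruxolitinib (edgeR adjusted p = 0.139) and was called higher without resistant replicate 4 (0.0336). PGR was at or under the detection floor in both groups. GATA3 rose by 0.55, FKBP5 by 0.24 and KRT18 by 0.22, while KRT14 was not called. KRT8 was not called by edgeR (adjusted p = 0.222), but was called higher with library size alone (0.00698), a mean log2 CPM of at least 1 (0.0388), DESeq2 (0.0386) and the GC and length offsets (log2 0.22, 0.000537). VIM stood at 827 ± 45.3 and 979.8 ± 39.2 CPM (edgeR adjusted p = 0.21) and was called higher without parental replicate 4 (0.00318), with no low-count filter (5.98e-05), by limma-voom (0.00534) and in a fit of the 8 libraries compared (0.000534). Luminal markers rose in 8 of 31 and fell in 7 (camera adjusted p = 0.767), androgen receptor targets rose in 4 of 25 and fell in 8 (0.668), and estrogen receptor targets rose in 3 of 34 and fell in 8 (0.402). Among them the EGFR ligand gene AREG fell from 186 ± 33 to 93.1 ± 6.32 CPM. Mesenchymal markers rose in 7 of 31 and fell in 15, or 8 and 15 adjusted over the list alone (camera adjusted p = 0.103), and the list was called lower without resistant replicate 2 (0.0357) or ruxolitinib replicate 2 (0.0409).

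The remaining lists were not called by camera. Rises and falls were 9 and 10 of 39 for NF-kB genes, 2 and 8 of 20 for neuroendocrine markers, 5 and 9 of 30 for stem markers, 9 and 9 of 32 for apoptosis regulators, 9 and 6 of 41 for growth factor receptors and ligands, 2 and 6 of 26 for cholesterol synthesis, 6 and 11 of 38 for steroid receptor coregulators, 4 and 2 of 9 for fibroblast markers, 2 and 3 of 12 for endothelial markers and 2 and 2 of 9 for leukocyte markers. Cell cycle inhibitors with p53 targets rose in 5 of 31 and fell in 6, and CDKN1A, an inhibitor of cyclin-dependent kinases, fell by 0.86. Fatty acid synthesis genes rose in 5 of 31 and fell in 13 (camera adjusted p = 0.073), and the list was called lower without resistant replicate 2 (0.0412) or ruxolitinib replicate 2 (0.0306). Oxidative phosphorylation genes rose in 2 of 36 and fell in 12 (camera adjusted p = 0.1, and 0.749 with an estimated correlation). The list was called lower without ruxolitinib replicate 1 (0.0455), but with the GC and length offsets 5 members rose and 6 fell (0.546). Adjusted over the list alone, rises and falls became 9 and 11 for NF-kB genes, 3 and 8 for neuroendocrine markers, 10 and 9 for apoptosis regulators, 2 and 4 for cholesterol synthesis, 2 and 4 for leukocyte markers, 5 and 7 for cell cycle inhibitors and 5 and 15 for fatty acid synthesis. Log2 changes with ruxolitinib fell with GC content across 12230 genes (Spearman −0.341), and with GC and length offsets, added after the data were seen, 79.0% of the calls were kept.

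**Figure D2:**
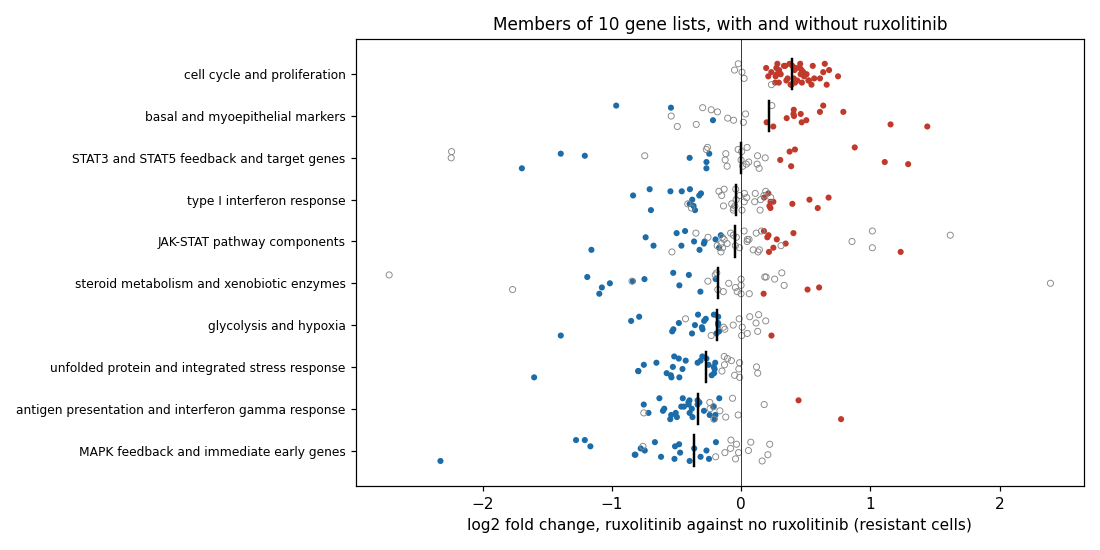
Log2 fold change with ruxolitinib in resistant cells on the horizontal axis for the members of 10 gene lists, with filled points for genes called by edgeR, open points for genes not called, and a bar at each list's median. In the cell cycle list 44 members were called higher and 0 lower, and in the MAPK list 20 were called lower and 0 higher.

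Whether ruxolitinib moved resistant cells back toward the parental state was asked by setting both comparisons side by side. Across all genes called in the first comparison the median return was near 0, while single genes moved back toward the parental level. ITGA1 went from 0.0383 ± 0.0281 CPM in parental cells to 95.8 ± 18.7 in resistant cells and 27.3 ± 1.63 with ruxolitinib. TIMP1 stood at 1.54 ± 0.357, 489 ± 83.5 and 151 ± 6.38 CPM, and THBD at 1.96 ± 0.187, 140.4 ± 16.4 and 44.3 ± 5.43 CPM. GDF15, at 30.8 ± 1.86, 88.2 ± 13.6 and 29.04 ± 1.52 CPM, stood near the parental level with the drug. The other genes with the largest opposed products were ARC, MMP9, HSPA6, PCBP3, LAPTM5, CTSW and the pseudogene HCG4B, whose reads may belong to HLA genes.

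Both comparisons called 6469 genes by edgeR, 3024 with opposite and 3445 with the same sign. Of the opposed genes, 1977 rose in resistant cells and fell with ruxolitinib, where independent lists would share 1769, and 1047 fell and then rose, where independent lists would share 1336. Rises in both numbered 1808 (1405 for independent lists) and falls in both 1637 (1682). Because the comparisons share the resistant libraries, independent lists are not the no-change value. With these libraries split, 1502 to 2043 genes rose and then fell (1247 to 1659 for independent lists) and 729 to 1060 fell and then rose (1148 to 1559). Rises in both were then 1725 to 2258 (1195 to 1632) and falls in both 1044 to 1384 (1198 to 1585). Across the 21296 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.0556. The mean was −0.474 for simulated unchanged groups, which held 20900 genes on average. The simulation also removed the difference between parental and resistant cells, so its r is not the value expected without a drug effect. No conclusion is drawn from the gap between the 2 values of r. With the resistant libraries split between the comparisons r was −0.00848 to 0.0790. The sign turned without resistant replicate 2 (r = −0.0289), and r was also lower without resistant replicate 1, 3 or 4, with a highest value of 0.0708 with 1 library left out. By DESeq2 r was −0.0924, but that fit started from 42328 genes without the low-count filter, so the methods were not compared on the same genes. The covariance was 0.118, against −0.0503 in the simulation and −0.0203 to 0.194 in the splits. The median return toward the parental level over all genes called in the first comparison was −0.728%, and −1.68% to 0% in the splits. Among the 3024 opposed genes the median change was 1.26 in resistant cells and 0.374 with ruxolitinib, in log2 size.

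**Figure D3:**
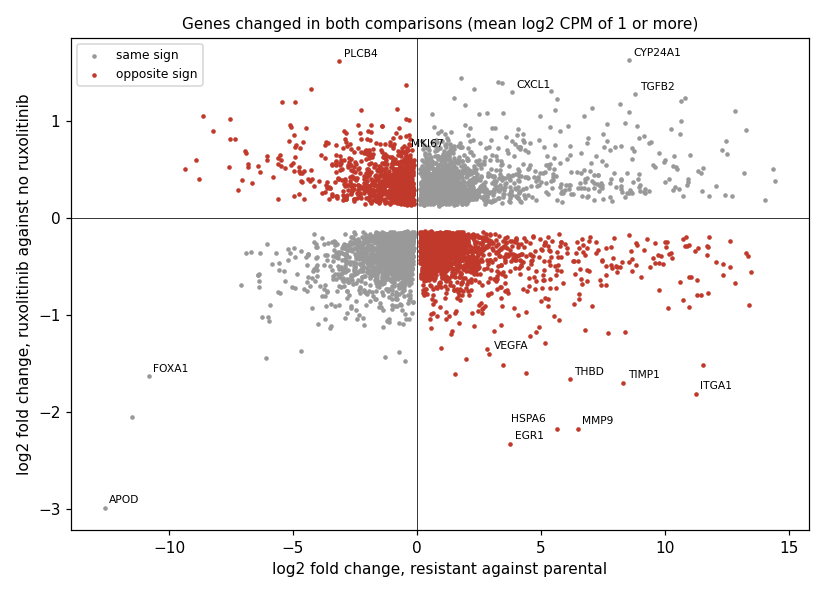
Log2 fold change of resistant against parental cells on the horizontal axis and of ruxolitinib against no ruxolitinib on the vertical axis, for 5430 genes called by edgeR in both comparisons with a mean log2 CPM of at least 1. Signs were opposite for 2574 genes and the same for 2856, and the vertical range is far narrower than the horizontal one.

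The last comparison asked how far ruxolitinib-treated resistant cells remained from parental cells. They remained apart by about as many genes as untreated resistant cells. By edgeR 9467 genes rose and 9213 fell, or 87.7% of those tested, and 6522 rises and 6547 falls were at least 2-fold. Of the 18628 genes called in the first comparison, 17526 (94.1%) were called here with the same sign. Of the 3024 opposed genes, 503 were no longer called against parental and 125 were called past the parental level.

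The 9 lists called higher and 3 called lower in resistant cells were called in the same direction with ruxolitinib, and the cell cycle list was called in addition, with 34 of 49 members up and 9 down (camera adjusted p = 0.00263, and 0.614 with an estimated correlation). Luminal markers fell in 28 of 31 and rose in 2 (camera adjusted p = 1.13e-08), and this call alone held with an estimated correlation (adjusted p = 0.0102). Mesenchymal markers rose in 27 of 31 and fell in 4 (camera adjusted p = 5.22e-06), antigen presentation genes rose in 36 of 39 and fell in 3 (1.75e-08), and MAPK feedback genes rose in 28 of 33 and fell in 4 (5.22e-06). Unfolded protein response genes rose in 25 of 35 and fell in 6 (camera adjusted p = 0.000636), and androgen receptor targets rose in 8 of 25 and fell in 16 (0.0735). Oxidative phosphorylation genes were not called by camera (adjusted p = 0.171), but were called lower with the GC and length offsets (0.0193) and by fry (1.63e-05). Counts adjusted over the list alone were the same as those over all genes for every list here.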

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

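The tests of GC offsets, of runs of silent genes and of carryover in parental replicate 4 were chosen after the result was seen, and the other splits, the thinning to equal depth and the test without the most abundant genes were chosen before. Within groups of 4, a library was singled out when its gap to the nearest other library took up nearly the whole range of the group by Dixon's test. This was applied to 137 genes and 5 library measures in 426 groups, of which 35 passed. The 426 include groups with 0 counts in every library, such as HACD4 in resistant cells, where the test gives no value. A group with counts in only 1 library, such as CAV1 in parental cells, passes whatever the count. The value of 21.3, which is 1 in 20 of the 426, is therefore not a valid chance value. No conclusion is drawn from the number that passed. Of the 35, 11 were in parental replicate 4, 6 in parental replicate 2 and 6 in ruxolitinib replicate 2.

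In parental replicate 4 the values that stood apart were 0.0307 CPM for COL8A1, 0.138 for IL6, 1.23 for PHLDA1, 0.307 for MMP9, 0.0460 for LAPTM5, 0.874 for VIM, 0.322 for TGFB2, 0.0307 for IL7R and 1.13 for MMP1, together with 484.8 for PADI2 and 227 for IGFBP2. In parental replicate 2 they were 0.0387 CPM for CAV1, 341.6 for IGFBP5, 331 for GATA3, 280.1 for STAT3, 31.4 for HACD4 and a mitochondrial share of 12.3% of counts. In parental replicate 1 they were 0.0414 CPM for ARC and 685.6 for CYP1B1. In ruxolitinib replicate 2 they were 100.7 CPM for IRS1, 0.880 for CDH3, 217 for JAK1, 0.0400 for KRT5, 210.7 for TGFB2 and 0.0400 for HOXC10. In the other ruxolitinib libraries they were 0.0350 CPM for PIP in replicate 1, 0.430 for TC2N and 19.4 for PTPRB in replicate 3, and 275 for PLAU and 47.9 for IL7R in replicate 4. In the resistant libraries they were 739 CPM for PHLDA1 and 26.9 for HOXB9 in replicate 2, 28.8 for ADAMTS1 in replicate 3, and 0.0384 for PGR and 0 for KRT5 in replicate 4.

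Transcripts abundant in resistant cells were present at a trace in parental replicate 4. Among 12 genes at 200 CPM or more in resistant cells and at 6 counts or fewer over the other 3 parental libraries, 11 were highest in parental replicate 4. The choice of genes low in the other libraries favours this outcome, and the same choice for parental replicates 1, 2 and 3 gave 0 of 2, 1 of 2 and 0 of 1 genes. Their 324 counts there came to 0.0732% of the resistant level, among them MMP1 (74 counts) and VIM (57). A candidate explanation is carryover of cells, RNA or reads from the resistant cultures, and no biological explanation was tested.

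Over the 35 splits of the 8 resistant and parental libraries, edgeR called 17967 genes in the real split and 0 in every other. Thus 1 of 35 splits gave as many, the smallest share these splits can give. Up to 247 genes passed an unadjusted p under 0.05 in the other splits. Those splits place the group difference within groups, which by itself keeps adjusted calls near 0. The result argues against chance for the number of calls, not for single genes. With every library thinned to 42277739 counts 17999 genes were called, and 18653 without mitochondrially encoded genes and the most abundant genes, which argues against depth or a few genes as the cause. Runs of silent genes were sought among protein-coding genes with a mean of at least 1 CPM in a group, so their members need not be adjacent. The longest run of neighbouring protein-coding genes silent in all 8 resistant libraries held 5 genes (HACD4, KLHL9, MTAP, CDKN2A and CDKN2B on chromosome 9, 20999515 to 22009363), against at most 2 in 1000 shuffles of gene order (permutation p = 0.001, the smallest they can give). The longest run silent in all 4 parental libraries held 7 genes (PSG1, PSG6, PSG2, PSG5, PSG4, PSG9 and CD177 on chromosome 19, 42866464 to 43363172), against at most 4 in the shuffles (permutation p = 0.001, again the smallest). Other runs silent in all 8 resistant libraries held 3 genes each, IRX4, IRX2 and IRX2-DT on chromosome 5 and GPC4, GPC3 and CCDC160 on chromosome X. In all 4 parental libraries the other runs of 3 were FLRT2, GALC and GPR65 on chromosome 14 and SPANXC, SPANXA1 and SPANXD on chromosome X. These parental runs were no longer than in the shuffles. DNA lost from resistant cells cannot give the runs silent in parental cells. The shuffles treat neighbouring genes as independent, so a cluster of related genes that are silent together, such as the PSG genes, can exceed them without a special event. The runs could come from another cell population, lost DNA for those silent in resistant cells, or silencing, which cannot be told apart here. A change of state under long enobosarm exposure stays open and untested.

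The list calls were weighed against the same splits. For resistant against parental cells 12 lists were called and at most 11 in another split (1 of 35), a margin of 1 list, which argues only weakly against chance for their number. For ruxolitinib against no ruxolitinib 7 lists were called and 9 in another split (2 of 35), and for ruxolitinib-treated against parental cells 13 were called and 13 in another split (2 of 35), so chance cannot be excluded for these counts of lists. Splits with 3 libraries of a group on a side keep part of the group difference and are not a no-change value. They gave 7 to 11, 3 to 9 and 8 to 13 lists in the 3 comparisons, and the 18 splits with 2 and 2 gave at most 2, 6 and 1. For ruxolitinib against no ruxolitinib and ruxolitinib-treated against parental cells, edgeR called 7233 and 18179 genes in the real splits and 0 in every other (1 of 35 each). Up to 2462 and 147 genes passed an unadjusted p under 0.05 in the other splits. Because the other splits place the group difference within groups, their 0 adjusted calls do not exclude chance for single genes.

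With ruxolitinib, cell cycle genes were higher and MAPK feedback and stress response genes were lower, while log2 changes fell with GC content (Spearman −0.341, and −0.00193 after offsets). None of these lists was called with an estimated correlation (camera adjusted p = 0.259, 0.0927 and 0.0805). With GC and length offsets 44 cell cycle genes were called higher and 0 lower, 18 MAPK feedback genes lower and 3 higher, and 22 stress response genes lower and 1 higher. This argues against GC content or length as the whole cause. With all libraries thinned to equal depth the counts were 44, 20 and 23, which argues against depth. The number of lists was reached by 1 other split (9 lists), which kept 3 libraries of a group on a side, and an effect of the drug stays open as a hypothesis.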

How the results depend on the processing

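The GC and length offsets, the 1 CPM filter and the joint omission of parental replicate 4 and resistant replicate 2 were chosen after the data were seen. Of 1758 values for 84 named genes in resistant against parental cells, 1758 kept their direction and side of the threshold. With ruxolitinib, 1483 of 1507 values for 72 genes did, 8 lost and 15 gained a call, and TYK2 reversed to a log2 change of 0.0166 with GC and length offsets (edgeR adjusted p = 0.817). The cause was not tested.

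Requiring a mean log2 CPM of at least 1 left 12287 genes, so fewer were called, with 5603 rises and 5561 falls in resistant against parental cells (2954 and 2957 at least 2-fold) and 5650 and 5562 in ruxolitinib-treated against parental cells (3057 and 3076). With ruxolitinib, 38 rises and 60 falls were at least 2-fold, and 121 and 114 with the 1 CPM filter. With parental replicate 4 and resistant replicate 2 left out together, ruxolitinib gave 3233 rises and 3729 falls, and resistant against parental cells 9423 and 8992.

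With an estimated correlation, camera called 0 lists up and 1 down in resistant against parental cells (5 and 1 at an unadjusted p under 0.05), 0 and 0 with ruxolitinib (2 and 3) and 0 and 1 in the last comparison (4 and 2). Fry, which does not compare a list with other genes, called 16 up and 9 down, 3 and 13 with ruxolitinib, and 16 and 9. It reversed fibroblast markers in resistant against parental cells (adjusted p = 0.00792) and fatty acid synthesis in the last comparison (0.00851). The cause was not tested.

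The DESeq2 fit had no low-count filter, so its values here rest on a different set of genes. The correlation of changes was −0.0924 by DESeq2, −0.0289 to 0.0708 with 1 library left out, and −0.00456 and −0.00848 with resistant replicates 1 and 2 or 2 and 3 in the first comparison. The median return was 0% by DESeq2, −0.872% to 0% with 1 library left out, and −1.68% and 0% with replicates 1 and 4 or 2 and 3. The cause was not tested. Leaving out 1 library gave 2721 to 3274 rises and 3170 to 3984 falls with ruxolitinib.

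After each gene's group mean was subtracted, replicates of the same number in different groups correlated at −0.123 to 0.11 across genes. Pairs of unlike number correlated at −0.212 to 0.154, so the numbers gave no sign of pairing. With the number as a block, 9484 genes rose and 9005 fell in resistant against parental cells, and 2963 rose and 3744 fell with ruxolitinib. The filter at a mean log2 CPM of 1 and the GC offsets shifted the log2 changes of shared genes in resistant against parental cells by a median of −0.135 and −0.143. The median log2 change of all genes tested went from 0.0573 to 0.00763 and to −0.125. Genes near the floor, such as ESR1 and PGR in resistant cells, are limited by depth.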

Other observations

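The gene families below were chosen after their values were seen, and their directions were the same under the 3 scalings. In resistant against parental cells, edgeR called 20 of 27 tested HOX genes lower and 7 higher. HOXC10 stood at 134 ± 6.93 CPM in parental cells and at 0 counts in resistant cells, and HOXB9 rose from 0.0277 to 22.2 ± 3.13 CPM. All 13 mitochondrially encoded protein genes fell, with a median log2 change of −2.32, MT-CO3 from 9295 to 743 CPM and MT-ND4 by 0.84. The 10 tested PSG genes, which are near-identical copies, rose, and 7 of them rose again with ruxolitinib, with PSG4 at 0 counts, 16.7 CPM and 35.9 CPM in parental, resistant and ruxolitinib-treated cells.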
